A study of Mus musculus with 18 samples.

How the data were processed

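Per the submitters' processing notes, reads were aligned to mm10 with HISAT2 2.2.1 and quantified with StringTie 2.1.6. The authors deposited a table of estimated counts for 57180 genes and another for 149132 transcripts, each with a column per library and a mean column per group. Of the genes, 25535 were at 0 in all 18 libraries. Of the deposited gene values above 0, 76.2% were whole numbers, and the counts were rounded before edgeR. Each mean column differed from the mean of its 3 libraries by at most 3.3e-05, and summed transcript counts differed from gene counts by at most 0.06. Of the gene identifiers, 90.7% were found in GENCODE M21, holding 99.25% of the counts, so the authors' annotation is not the M21 release from which coordinates are given here. Doses, times, the siRNA sequences and the strand used for counting are not given in the sources used here, so genes that overlap on opposite strands are uncertain.

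The 18 libraries were fitted together in edgeR 4.0.16 with TMM normalisation (factors 0.925 to 1.07), a mean per group and quasi-likelihood tests with 12 residual degrees of freedom. Genes were kept by edgeR's filterByExpr with a minimum count of 10, which left 15832 genes and at least 99.91% of the counts of each library. The biological coefficient of variation was 6.01%. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the quasi-likelihood F statistic. CPM values use TMM-scaled totals of the genes tested, and those of cell-type marker medians TMM-scaled totals of all genes. R 4.3.3, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.

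The comparisons, the threshold, the alternatives and the rule for naming genes were chosen before the data were examined. That rule names Itgav in every library and a panel of 17 genes, 1 of which is not reported here: Itgav, Itgb1, Itgb3, Itgb5, Itgb8, Itga5, Acta2, Myh11, Tagln, Cnn1, Col1a1, Fn1, Eln, Klf4, Spp1 and Mki67. For each of 5 comparisons between a pair of groups it adds the 5 largest positive and 5 largest negative log2 fold changes among called genes with a mean of at least 5 CPM, no overlap between the groups and an ordinary gene symbol. For each of 2 differences between media it adds the 5 positive and 5 negative genes with the smallest p. From each list with at least 3 called members it adds up to 4 with the smallest p. Members on the smaller side of a list, members of lists with fewer than 3 called genes, and members that did not pass were named after their values were seen.

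Pathway lists were tested with limma's camera on voom values at its preset inter-gene correlation of 0.01, adjusted over the 17 lists within a comparison, and again with an estimated correlation. The lists were contractile smooth muscle, modulated smooth muscle, extracellular matrix, matrix proteases and inhibitors, TGF-β and SMAD targets, ERK targets, cell cycle, integrin subunits, focal adhesion, YAP and TEAD targets, inflammatory and NF-κB genes, interferon response, cholesterol synthesis, ATF4 and ER stress, hypoxia and glycolysis, p53 targets, and osteochondrogenic genes. Markers of 9 other cell types were listed as well: endothelial, macrophage, adventitial fibroblast, adipocyte, lymphocyte, Schwann cell, mesothelial, cardiomyocyte and erythroid. No erythroid marker passed the low-count filter. All lists were written from general knowledge of the genes.

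Alternatives tried were no low-count filter, a mean of at least 1 CPM, DESeq2 size factors within edgeR, a block for the replicate number, summed transcript counts, DESeq2 itself, a fit of only the groups compared, and leaving out each library of a comparison in turn. The fit was tested on simulated data. For TGF-β in scramble cells, 67, 67 and 66 genes were changed 1.5-fold, 2-fold and 4-fold, up or down, in the TGF-β group. Of these 68.7%, 80.6% and 95.5% were recovered, and 4.68% of 171 calls were false. For the difference of the siRNA effect between TGF-β and unstimulated cells the shares were 50.7%, 79.1% and 81.8%, and 7.24% of 152 calls were false. Far fewer genes were changed in these simulations than were called in the data (7639 and 3678). The rates therefore need not hold for the real comparisons. Correlations between effects that share control libraries were compared with simulations of 20 sets of unchanged groups.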

Results

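RNA was sequenced from cultured smooth muscle cells of the mouse thoracic aorta (C57BL/6), in 6 groups of 3 libraries. Cells had received either a scramble siRNA, a control without an intended target, or an siRNA against Itgav, and were then left unstimulated or given TGF-β or PDGF-BB. Itgav encodes integrin αV, a receptor chain that binds matrix proteins and latent TGF-β, and the series title names it as a possible target in aortic aneurysm and dissection. TGF-β is known to raise contractile and matrix genes in these cells, and PDGF-BB to lower contractile genes. The deposited counts of the largest library totalled 21592916, and 15832 genes were tested. In a principal component analysis the first component held 40% of the variance and placed the 6 TGF-β libraries at 58.4 or above and every other library at -2.73 or below. The second component held 27.2% and placed all 9 scramble libraries at 15.2 or above and all 9 Itgav siRNA libraries at -18.1 or below. No pair of replicates was as alike as counting noise alone would make it, with a chi-square per degree of freedom of 2.25 in the closest pair. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical. In what follows, an error after a CPM value is an SD over 3 libraries and an error after a log2 fold change is a standard error. Gene calls are those of edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, and list calls those of camera at the same threshold. Counts of list members adjusted over the list alone were the same as those over all genes unless given.

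Itgav (ENSMUSG00000027087, chromosome 2, 83724397 to 83806916 on the plus strand, GENCODE M21 on GRCm38) was low in every library that had received its siRNA. In unstimulated cells it stood at 300, 326 and 323 CPM in the scramble libraries and at 14.8, 14.1 and 16.4 CPM in the siRNA libraries, so that 4.78% of the scramble mean remained. With TGF-β the scramble libraries held 548, 553 and 472 CPM and the siRNA libraries 26.1, 29.7 and 25.3 CPM, a remainder of 5.15%. With PDGF-BB the values were 307, 336 and 319 CPM against 19.1, 23.9 and 25.5 CPM, a remainder of 7.1%. TGF-β itself raised Itgav 1.66-fold in scramble cells (log2 fold change 0.73 ± 0.072, edgeR adjusted p = 1.9e-08), while PDGF-BB left it within the replicate spread (0.02 ± 0.072, edgeR adjusted p = 0.86).

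**Figure D1:**
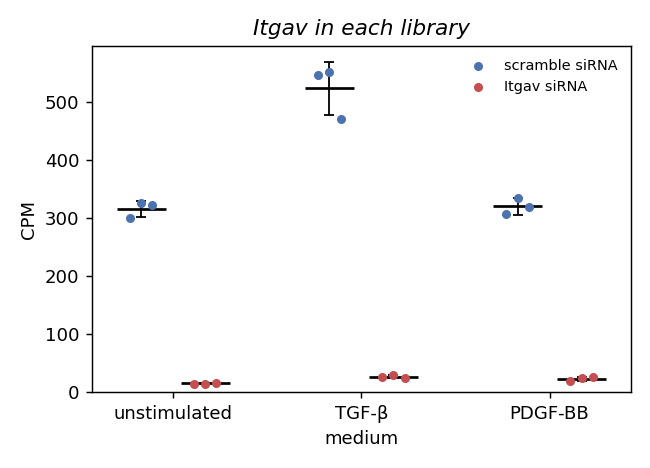
Itgav in CPM, counts scaled to library size (vertical axis) in the 6 groups (horizontal axis), with a point per library, a line at the mean and bars of 1 SD over 3 libraries. The 9 siRNA libraries lie between 14.1 and 29.7 CPM and the 9 scramble libraries between 300 and 553 CPM.

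The first comparison asked what TGF-β changed in scramble cells. Acta2, the smooth muscle actin of the contractile apparatus, rose 3.97-fold, from 1060 ± 32.9 to 4230 ± 203 CPM (log2 fold change 1.99 ± 0.042). Tagln and Cnn1, actin-binding proteins of contractile cells, rose 3.06-fold (1.61 ± 0.055) and 2.68-fold (1.42 ± 0.12), and the smooth muscle myosin heavy chain Myh11 rose 1.34-fold (0.42 ± 0.11). Matrix genes rose too: Eln, which encodes elastin, went from 352 ± 10.2 to 5700 ± 236 CPM (16.2-fold, 4.02 ± 0.055), Col1a1 rose 3-fold and Fn1 1.64-fold. Spp1, which encodes osteopontin and marks modulated smooth muscle, rose 3.03-fold to 230 ± 20.8 CPM (1.60 ± 0.072), while the transcription factor Klf4 (-0.84 ± 0.046) and Mki67, a marker of dividing cells (-1.44 ± 0.07, 166 ± 6.8 to 61 ± 3.32 CPM), fell.

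Among the genes with the largest changes, the cadherin Cdh10 rose from 0.159 to 23.6 ± 3.14 CPM, Olr1, a receptor for oxidised lipoprotein, from 0.221 to 17.5 ± 0.534 CPM, and Rgs4, a regulator of G-protein signalling, 65.7-fold to 126 ± 7.05 CPM. Fxyd6 and the prolactin family member Prl3a1 completed the 5 largest rises, with log2 fold changes of 6.58 ± 0.25 and 6.49 ± 0.24. The 5 largest falls were those of the flavin monooxygenase Fmo2 (38.3 ± 3.82 to 0.869 ± 0.101 CPM), the aldehyde dehydrogenase Aldh3a1 (-4.01 ± 0.14), Selenbp1 (-3.77 ± 0.11), Clic5 (-3.68 ± 0.21) and Thsd4 (-3.55 ± 0.1). For each of these 10 genes the 3 libraries of one group all lay above the 3 of the other. The weakest of the changes named so far, that of Myh11, had an adjusted p of 0.0027 in edgeR's test. In all, 7639 genes passed, 3710 higher and 3929 lower, of which 870 and 1076 changed at least 2-fold.

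Of the 39 tested extracellular matrix genes, 29 rose, 6 fell and 4 did not pass (30 and 6 adjusted over the list alone), with a median log2 fold change of 0.84 and an adjusted p of 3.2e-14 in camera. That call was lost at adjusted p = 0.089 with an estimated correlation. Postn (3.44), Mfap4 (3.37) and Col5a2 (2.29) rose most clearly beside Eln. Of 30 TGF-β and SMAD targets, 21 rose, among them Ltbp2 (3.90) and Pmepa1 (2.56), 7 fell and 2 did not pass, with a median of 0.69 (camera adjusted p = 9.2e-06, and adjusted p = 0.0028 with an estimated correlation). Integrin subunits rose as a list, 12 of 17 higher and 3 lower, with a median of 0.61 (camera adjusted p = 4e-06, and adjusted p = 0.011 with an estimated correlation): Itga4 (2.55), Itga11 (2.31), Itgb3 (2.30 ± 0.063), Itgb5 (1.25 ± 0.039), Itga5 (1.09) and Itgb1 (0.72) were higher, and Itga1, Itga8 and Itgb8 lower. Itgb8 changed by -0.75 ± 0.21 (edgeR adjusted p = 0.0047), a call that ended without scramble unstimulated replicate 2 (-0.47, adjusted p = 0.057). Of 40 cell cycle genes 38 fell and 2, Mcm6 and Tyms, did not pass, with Cdc20 (-1.75), Kif20a (-1.38) and Tpx2 (-1.31) among them and a median of -1.19 (camera adjusted p = 1e-22, and adjusted p = 0.011 with an estimated correlation).

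In the contractile list 15 of 23 members rose, 6 fell and 2 did not pass, with a median of 0.42 (camera adjusted p = 0.00026, lost at adjusted p = 0.097 with an estimated correlation), and Synpo2 (1.49) and Tpm1 (1.19) were among those that rose. ATF4 and ER stress genes rose in 16 of 24 cases and fell in 4, led by the folate enzymes Aldh1l2 (3.55) and Mthfd2 (1.61) and the asparagine synthetase Asns (1.49), with camera adjusted p = 9.3e-06 and adjusted p = 0.14 with an estimated correlation. Of 14 osteochondrogenic genes 8 rose, including the cartilage genes Acan (5.77), Col2a1 (2.77) and Col11a1 (2.74), and 4 fell, including Ogn (-2.14), with camera adjusted p = 0.0087 and adjusted p = 0.097 with an estimated correlation. YAP and TEAD targets rose in 9 of 22 cases and fell in 4, with Ccn1 (0.91) and F3 (1.60) higher (camera adjusted p = 0.047, and adjusted p = 0.37 with an estimated correlation). Interferon response genes fell in 20 of 30 cases (21 adjusted over the list alone) and none passed as higher, with a median of -1.13, Gbp2 at -2.07 and Ifit3 at -1.34 (camera adjusted p = 0.0087, and adjusted p = 0.62 with an estimated correlation). Scramble unstimulated replicate 1 already lay near the TGF-β level for some of these genes: Ifit1 stood at 8.66 CPM there, at 49.8 and 44.7 CPM in the other 2 libraries of its group and at 6.4 to 9.49 CPM with TGF-β. Among p53 targets 10 of 17 fell (11 adjusted over the list alone), with Sesn1 at -0.92, and Fas, Plk2 and Rrm2b rose (camera adjusted p = 0.03, and adjusted p = 0.1 with an estimated correlation). The other 7 lists did not pass, and for 3 of them camera pointed up against another measure: against the mean for matrix proteases and inhibitors (median 0.25, mean -0.15), against the median for cholesterol synthesis (-0.01, mean 0.14) and against both for hypoxia and glycolysis (-0.1, mean -0.17).

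Markers of other cell types moved as well. Of 5 tested mesothelial markers 4 fell, including the keratin Krt19 (-2.04) and the uroplakins Upk1b (-1.63) and Upk3b (-0.66). Of 5 tested macrophage markers 4 fell, including Lyz2 (-1.14), and Ptprc rose. Of 10 endothelial markers the transcription factor Erg rose from 7.01 to 45.4 CPM and Egfl7 (-1.44), Esam (-1.04), Kdr and Tie1 fell. Of 10 adventitial fibroblast markers 5 fell, including Cd34 (-1.50) and Pdgfra (-0.82), and Pi16, Serpinf1 and Gsn rose.

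PDGF-BB in scramble cells lowered the 4 contractile genes of the panel, which TGF-β had raised. Acta2 fell from 1060 ± 32.9 to 393 ± 12.5 CPM (log2 fold change -1.44 ± 0.042), Tagln from 720 ± 9.46 to 333 ± 11.4 CPM (-1.11 ± 0.055), Myh11 from 22.9 ± 1.7 to 7.78 ± 1.62 CPM (-1.56 ± 0.12) and Cnn1 to 8.83 ± 1.16 CPM (-1.07 ± 0.13). Spp1 rose 8.3-fold to 631 ± 59.1 CPM (3.05 ± 0.074). The protease inhibitor Serpinb2 rose 47-fold to 20.7 ± 1.57 CPM and the matrix-degrading enzyme Mmp3 21.5-fold to 32.8 ± 3.4 CPM, followed by the receptor gene Npy4r (3.69 ± 0.21) and Nptx1 (3.57 ± 0.27). Rtn1 (-4.67 ± 0.26), Kank4 (-4.22 ± 0.23), Ptprz1 (-3.29 ± 0.22), the collagen-binding proteoglycan Fmod (239 ± 3.63 to 28.5 ± 1.16 CPM) and Fmo2 (-3.06 ± 0.086) fell furthest. Each change in this paragraph had an adjusted p of 1.3e-06 or less in edgeR's test.

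Counts passing the test were 2676 higher and 3038 lower, 5714 in all, with 450 and 437 of them at least 2-fold. Scramble PDGF-BB replicate 1 stood apart from the other libraries of its group on the fourth component (23.6 against 0.879 and 5.05), and without it 4821 genes passed. Of the panel, Eln (-0.43), Itgb5 (-0.57) and Klf4 (-0.54) fell, Itgb3 (0.28) and Itga5 (0.24) rose, and Fn1 (0.02), Itgb1 (0.05), Itgb8 (-0.02) and Col1a1 (-0.13) did not pass. Col1a1 passed in 4 alternative fits, among them those without scramble unstimulated replicate 1 (-0.17) and without scramble PDGF-BB replicate 2 (-0.19). Mki67 fell by 0.22 on the log2 scale (edgeR adjusted p = 0.014), a call lost without scramble unstimulated replicate 3 (adjusted p = 0.061).

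Genes downstream of ERK signalling rose in 24 of 30 cases (25 adjusted over the list alone), with Hmga1 (2.44), Dusp6 (1.02), Hmga2 (0.95) and Ccnd1 (0.69) as examples and a median of 0.62. Spry1, Fos and Dusp1 fell. In the fit without a replicate block this was the list call that held in this comparison with an estimated correlation (camera adjusted p = 3e-13, and adjusted p = 2.6e-05 with an estimated correlation). Contractile genes fell in 16 of 23 cases, Cald1 (-0.85) and Csrp1 (-0.69) among them, while Des and Mylk rose (median -0.68, camera adjusted p = 4.5e-07, lost at adjusted p = 0.05 with an estimated correlation). Cell cycle genes fell in 21 of 40 cases and rose in none, by a small median of -0.22, with Top2a at -0.51 and Cdk1 at -0.50 (camera adjusted p = 6.1e-05, and adjusted p = 0.27 with an estimated correlation). Osteochondrogenic genes fell in 9 of 14 cases (10 adjusted over the list alone), led by Bmp4 (-1.78) and Ogn (-2.2), while Spp1 and Mgp rose (camera adjusted p = 0.0019, and adjusted p = 0.055 with an estimated correlation). Extracellular matrix genes fell in 19 of 39 cases (20 adjusted over the list alone) and rose in 11, with the crosslinking enzyme Lox at -1.45 and Fbln5 at -1.13 (camera adjusted p = 0.0098, and adjusted p = 0.49 with an estimated correlation). Focal adhesion genes fell in 14 of 28 cases and rose in 6 (8 adjusted over the list alone), with Vcl at -0.82 and Nedd9 at -0.96 (camera adjusted p = 0.0098, and adjusted p = 0.21 with an estimated correlation).

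YAP and TEAD targets fell in 11 of 22 cases, Ccn1 (-0.94) and Tgfb2 (-0.99) among them, and Dock5, Axl, Igfbp3, Myof and Asap1 rose (camera adjusted p = 0.015, and adjusted p = 0.31 with an estimated correlation). Modulated smooth muscle genes rose in 9 of 16 cases, with Mgp (1.98), Vcam1 (1.43) and Cd44 (1.34) beside Spp1, and fell in 6 (camera adjusted p = 0.019, and adjusted p = 0.14 with an estimated correlation). Cholesterol synthesis genes rose in 7 of 20 cases (8 adjusted over the list alone), with Insig1 at 0.35, and Sqle and Sc5d fell (camera adjusted p = 0.037, and adjusted p = 0.33 with an estimated correlation). The remaining 8 lists did not pass. In 5 of these camera pointed down while the mean, the median or both lay above 0: matrix proteases and inhibitors (median -0.02, mean 0.43), TGF-β and SMAD targets (-0.12, 0.04), integrin subunits (0.05, -0.03), inflammatory genes (0.09, 0.23) and ATF4 and ER stress genes (-0.02, 0.08). Among other cell types, the mesothelial markers Krt19 (1.51), Msln (1.76) and Upk1b rose and Upk3b (-1.91) fell, and of 10 adventitial markers 5 rose, including Dpt (2.38), Scara5 (1.23) and Cd34 (0.73), while Pdgfra (-0.77), Clec3b and Lum fell. Of the macrophage markers Cd68 averaged 2.08 CPM in unstimulated and 9.4 CPM in PDGF-BB scramble cells, while Lyz2 averaged 9.7 and 5.88 CPM.

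**Figure D2:**
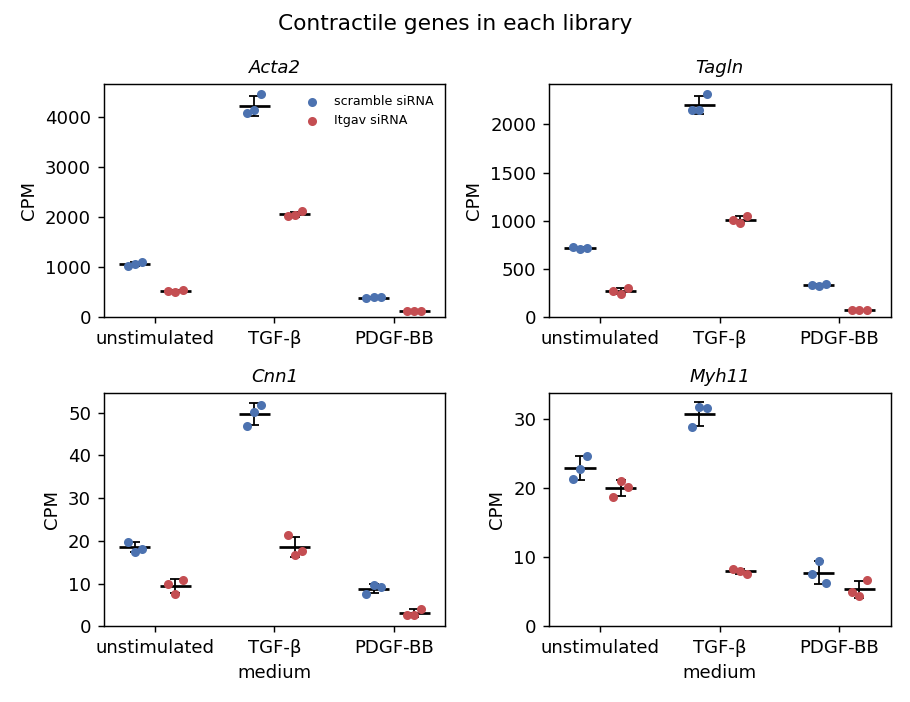
Acta2, Tagln, Cnn1 and Myh11 in CPM (vertical axes) in the 6 groups (horizontal axes), with a point per library, a line at the mean and bars of 1 SD over 3 libraries. Acta2 averaged 1060, 4230 and 393 CPM in unstimulated, TGF-β and PDGF-BB scramble cells and 524, 2060 and 125 CPM in the matching siRNA cells.

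Across all 15832 genes the log2 fold changes of TGF-β and PDGF-BB in scramble cells correlated with r = 0.144 (Spearman 0.0978), genes not being independent replicates. Both were measured against the same 3 libraries, and 20 simulations of unchanged groups against such controls gave a mean r of 0.481 with a highest of 0.518. The covariance was 0.0813 against a simulated 0.0225, a difference of 0.0588. Genes with the same sign made up 52.5%, against a simulated 66.4%. The simulated groups held no changed genes, whereas many genes changed here. A lower r or share than simulated therefore does not show that the responses were less alike than chance. Both stimuli raised 788 genes, where independent lists of those sizes would share 627.1, and both lowered 1153, where independent lists would share 753.9. Another 1635 of the 3576 genes called in both moved in opposite directions. The 3 control libraries leave no split with at least 2 in each part and were not split, so part of the excess of shared calls can come from the shared controls. Without scramble unstimulated replicate 3 the correlation was 0.22, and with a mean of at least 1 CPM it was 0.0452.

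The comparison of Itgav siRNA with scramble in unstimulated cells asked what changed with the siRNA in the absence of a stimulus. It cannot tell the loss of Itgav from other effects of the siRNA. The largest rises were those of interferon-stimulated genes, which cells make in response to viral RNA or interferon. Rsad2, an antiviral enzyme also called viperin, rose from 1.54 ± 0.353 to 224 ± 46 CPM (log2 fold change 7.19 ± 0.3), the guanylate-binding protein Gbp6 rose 58.8-fold to 116 ± 6.01 CPM and Oasl2 50.5-fold to 228 ± 20.7 CPM. For Mx1 the siRNA group held 1750 counts against 2 in the scramble group, a ratio of 958 with a 95% interval of 265 to 7920, and for Oas1g 655 counts against 1, a ratio of 717 with an interval of 128 to 28400. Both intervals cover counting error only. All 30 interferon response genes of the list rose, with a median log2 fold change of 4.77, and Ifit3 went from 78 to 3080 CPM (5.31 ± 0.19).

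Of the 4 contractile genes of the panel, 3 were lower. Acta2 (ENSMUSG00000035783, chromosome 19, 34241090 to 34255590, minus strand) fell from 1060 ± 32.9 to 524 ± 23 CPM (-1.02 ± 0.041), Tagln (ENSMUSG00000032085, chromosome 9, 45929619 to 45936058, minus strand) from 720 ± 9.46 to 273 ± 28.5 CPM (-1.40 ± 0.056) and Cnn1 by 0.98 ± 0.13 on the log2 scale, each with an adjusted p of 1.9e-06 or less in edgeR's test. Myh11 stood at 20 ± 1.2 against 22.9 ± 1.7 CPM and did not pass (edgeR adjusted p = 0.14), though it did with only the compared groups in the fit (-0.2). Among the other integrin chains of the panel, Itgb8, whose product pairs with integrin αV, rose from 3.44 ± 1.08 to 22.5 ± 0.965 CPM (2.72 ± 0.14), Itgb5 1.88-fold, Itgb3 1.69-fold and Itgb1 1.14-fold, while Itga5 did not move (0.00, edgeR adjusted p = 0.97). The largest falls after Itgav itself were those of Armcx2 (127 ± 4.65 to 9.23 ± 0.78 CPM), the folate hydrolase Folh1 (-2.92 ± 0.13), the RNA-binding protein Rbpms2 (-2.66 ± 0.087) and the G-protein subunit Gnal (-2.60 ± 0.15). Fn1 rose 1.55-fold, Eln 1.13-fold and Spp1 1.22-fold, Mki67 fell to 0.713 of the scramble level, and Klf4 rose by 0.16. Col1a1 fell by 0.16 on the log2 scale with edgeR adjusted p = 0.028, and without scramble unstimulated replicate 2 or 3, or siRNA unstimulated replicate 1 or 3, that value was 0.14, 0.073, 0.053 or 0.085.

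In all, 8457 genes passed, 4108 higher and 4349 lower, with 1024 and 620 at least 2-fold. The interferon call (camera adjusted p = 1.5e-21) was lost at adjusted p = 0.12 with an estimated correlation, these genes varying together between replicates; scramble unstimulated replicate 1 lay below the other 2 of its group in the plot of interferon genes. Members of the Ifit, Oas and Gbp families are near-identical copies in places, so the split of counts between Ifit3 and Ifit3b or between Oas1 genes is uncertain. Contractile genes fell in 15 of 23 cases, Myl9 (-1.45) among them, and Csrp1 (0.66), Itga8, Synpo2 and Mylk rose (camera adjusted p = 0.00075, and adjusted p = 0.12 with an estimated correlation). Focal adhesion genes fell in 22 of 28 cases, including the actinins Actn4 (-1.06) and Actn1 (-0.93) and the integrin activator Fermt2 (-1.20), and Tns2, Bcar1 and Pxn rose (median -0.51, camera adjusted p = 1.8e-08, and adjusted p = 0.019 with an estimated correlation). Cholesterol synthesis genes fell in 18 of 20 cases, led by Idi1 (-1.79), Sc5d (-1.30), Msmo1 (-1.22) and Hmgcs1 (-1.18), with a median of -0.62 (camera adjusted p = 1.4e-09, and adjusted p = 0.019 with an estimated correlation). Insig1, which holds back this pathway when sterols are plentiful, was the 1 member that rose.

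Cell cycle genes fell in 31 of 40 cases (32 adjusted over the list alone) and Mcm6 rose, with Mcm5 at -0.67, Mcm7 at -0.61 and Cdk1 at -0.56 (camera adjusted p = 4e-08, and adjusted p = 0.12 with an estimated correlation). Integrin subunits rose in 11 of 17 cases, and Itga3 (-0.53), Itga11 and Itga1 fell (camera adjusted p = 0.022, and adjusted p = 0.12 with an estimated correlation). Inflammatory and NF-κB genes rose in 12 of 20 cases, including the chemokine Ccl7 (3.81) and complement C3 (1.34), and fell in 6, including Ptgs2 (-0.97), with camera adjusted p = 0.049 and adjusted p = 0.12 with an estimated correlation. The other 10 lists did not pass: among them YAP and TEAD targets had 7 higher and 14 lower of 22, with Ankrd1 at -1.91, and TGF-β and SMAD targets 12 higher and 12 lower of 30, with Tgfbi at 2.45 and Inhba at -1. Camera pointed down for the ERK list (median 0.07, mean 0.08) and for the ATF4 and ER stress list (median -0.1, mean 0.11), where Slc7a11 rose by 2.77 and Psat1 fell by 1.47 on the log2 scale.

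Markers of other cell types moved with these groups. The median level of the 6 mesothelial markers was 16.9 CPM in scramble and 8.08 CPM in siRNA cells, with Upk1b at 80 and 34.8 CPM and Krt19 at -1.07. The median of 11 adventitial fibroblast markers was 1.94 and 3.91 CPM, with Pdgfra at 12.3 and 25 CPM, Scara5 at 1.89 and Cd34 at -0.79, and the median of 10 endothelial markers 8.1 and 6.28 CPM, with Pecam1 at -0.52. Schwann cell markers had a median of 0.707 and 1.44 CPM, Cdh19 rising by 2.86 while Mbp (-0.65) and S100b fell. Macrophage markers had medians of 0.0966 and 0.0432 CPM, adipocyte, lymphocyte and cardiomyocyte markers medians of at most 0.0559 CPM in any of the 6 groups, and erythroid markers at most 0.0169 CPM. Some members stood far above these medians. The adipocyte markers Fabp4 and Lpl averaged 12.3 and 14.8 CPM in scramble and 3.15 and 23.5 CPM in siRNA cells. The cardiomyocyte marker Tnnt2 averaged 14.6 and 11 CPM. Fabp4 was also lower with the siRNA under TGF-β (27.2 to 8.65 CPM) and PDGF-BB (27.5 to 10.6 CPM). Among the genes named for the siRNA comparisons, the annotated 3′ UTRs of Rbpms2, Plau, Adm, Parva, Tnfaip3 and Inhbb hold the sequence ACGTGAA, those of Idi1, Psat1, Inhba, Trp53inp1, Itga1, Itgb1, Itgb8, C3, Synpo2 and Slc22a23 hold GACTACA, and that of Ctsl holds TTCGGAT. The 3′ UTR of Itga8, which rose with the siRNA in unstimulated and PDGF-BB cells, also holds ACGTGAA. As means of the log2 fold change over the 3 media, Itgb8 (2.95), C3 (1.32), Ctsl (0.69), Itgb1 (0.33) and Synpo2 (0.2) were also higher. The other holders named here were lower. Of 13540 genes whose 3′ UTR was searched, 418 hold ACGTGAA, 932 hold GACTACA and 195 hold TTCGGAT. All 3 sequences also occur in the Itgav mRNA.

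**Figure D3:**
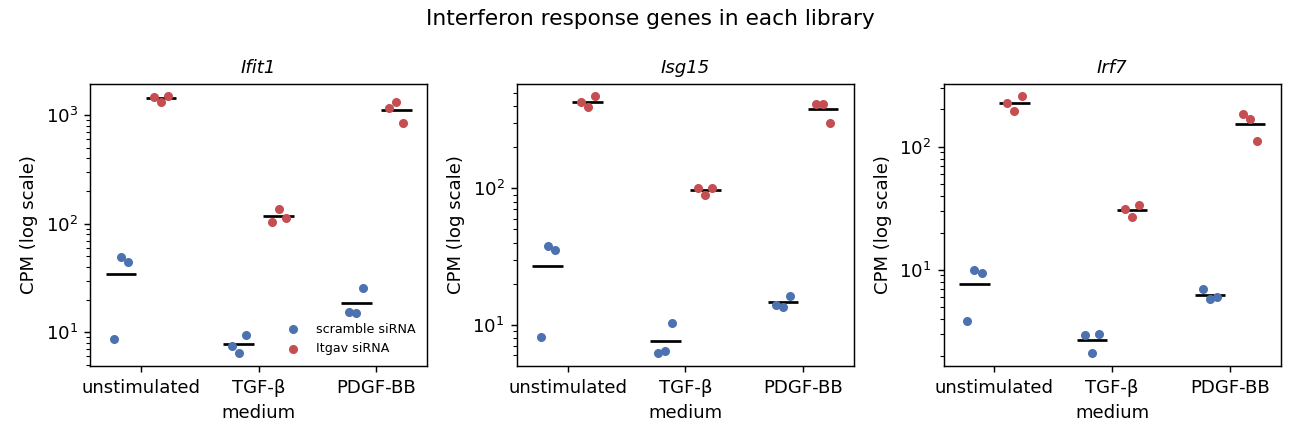
Ifit1, Isg15 and Irf7 in CPM (vertical axes, log scale) in the 6 groups (horizontal axes), with a point per library and a line at the mean of 3 libraries. Each siRNA group lies above the scramble group of the same medium, and all 30 interferon genes tested were higher with the siRNA in each medium.

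With TGF-β present, Itgav siRNA lowered 22 of the 23 contractile genes and none rose, Itga8 being the member that did not pass. Acta2 fell from 4230 ± 203 to 2060 ± 50 CPM (-1.04 ± 0.041), Tagln from 2200 ± 91.3 to 1010 ± 36 CPM (-1.12 ± 0.055), Cnn1 from 49.7 ± 2.56 to 18.6 ± 2.45 CPM (-1.42 ± 0.12) and Myh11 (ENSMUSG00000018830, chromosome 16, 14194535 to 14291372, minus strand) from 30.8 ± 1.66 to 7.96 ± 0.384 CPM (-1.95 ± 0.12). Myl9 (-1.67) and Lmod1 (-1.39) fell with them, and the list had a median of -1.04 (camera adjusted p = 2e-12, and adjusted p = 0.0046 with an estimated correlation). Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050, plus strand) rose from 230 ± 20.8 to 1520 ± 83.7 CPM (2.72 ± 0.071), Fn1 2.01-fold to 29600 ± 1280 CPM and Eln 1.47-fold to 8390 ± 157 CPM. Igfbp5, a secreted binder of insulin-like growth factors, rose 30.7-fold to 215 ± 23.8 CPM. Each change named in this paragraph with its error had an adjusted p of 2.7e-09 or less in edgeR's test.

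The other large rises were those of the retinoic acid binding protein Crabp2 (3.81 ± 0.16) and the interferon-stimulated genes Slfn8 (4.02 ± 0.31), Ifit1 (3.93 ± 0.39) and Oasl2 (3.83 ± 0.28). Folh1 (-4.05 ± 0.21), Nkain4 (-3.62 ± 0.094), Armcx2 (-3.39 ± 0.06) and Susd2 (-2.87 ± 0.2) fell furthest after Itgav. Itgb8 rose 5.17-fold, Itgb5 1.91-fold, Itgb3 1.88-fold, Itga5 1.46-fold, Itgb1 1.35-fold and Col1a1 1.32-fold, and Klf4, a transcription factor of smooth muscle modulation, fell to 0.595 of the scramble level. Mki67 (-0.06, edgeR adjusted p = 0.54) did not pass. In all 7662 genes passed, 3809 higher and 3853 lower, with 979 and 590 at least 2-fold.

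TGF-β and SMAD targets rose in 19 of 30 cases, including Tgfbi (3.37), Tgfb1 (2.11), Nrep (1.99) and Bhlhe40 (1.85), and Id2, Id1 and Inhba fell, with a median of 0.40 (camera adjusted p = 1.3e-06, and adjusted p = 0.0015 with an estimated correlation). Of these, Tgfb1 encodes the ligand itself and Bhlhe40 a repressor also driven by other signals. Focal adhesion genes fell in 19 of 28 cases (20 adjusted over the list alone), Tns1 (-0.95), Parva (-0.90), Actn4 (-0.84) and Actn1 (-0.71) among them (camera adjusted p = 1.7e-08, and adjusted p = 0.012 with an estimated correlation). Cholesterol synthesis genes fell in 15 of 20 cases (16 adjusted over the list alone), with Idi1 at -1.50 and Hmgcs1 at -1.07, and 3 rose, Insig1 (1.24) among them (camera adjusted p = 1e-06, and adjusted p = 0.032 with an estimated correlation). All 30 interferon response genes rose, with a median of 2.96 and Usp18 at 3.78 and Ifi44 at 3.43 (camera adjusted p = 1.5e-10, and adjusted p = 0.16 with an estimated correlation). Extracellular matrix genes rose in 23 of 39 cases (24 adjusted over the list alone), with Postn at 2.31 and Thbs2 at 1.25, and Tnc (-0.75), Col6a1, Col6a2 and Fbln5 fell (camera adjusted p = 0.00014, and adjusted p = 0.3 with an estimated correlation).

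Matrix proteases and inhibitors rose in 15 of 25 cases (16 adjusted over the list alone), with the inhibitor Timp3 (1.45) and the cathepsin Ctsl (1.15) among them, and 7 fell, including the inhibitor Timp2 (-0.90), so that enzymes and inhibitors stand on both sides (camera adjusted p = 0.0022, and adjusted p = 0.13 with an estimated correlation). Integrin subunits rose in 8 of 17 cases and Itga3 (-0.81), Itga1, Itga6 and Itga7 fell (camera adjusted p = 0.013, and adjusted p = 0.12 with an estimated correlation). Among p53 targets 10 of 17 fell, with Trp53inp1 at -0.87, and Btg2 rose (camera adjusted p = 0.013, and adjusted p = 0.087 with an estimated correlation). Hypoxia and glycolysis genes rose in 10 of 20 cases, with the glucose transporter Slc2a1 at 1.01 and Bnip3 at 0.77, while Adm (-2.21), Ldha and Pgam1 fell (camera adjusted p = 0.016, and adjusted p = 0.3 with an estimated correlation). Modulated smooth muscle genes rose in 10 of 16 cases, with Mgp at 2.74, Vcam1 at 1.34 and Cd44 at 0.89, and fell in 6 (camera adjusted p = 0.019, and adjusted p = 0.12 with an estimated correlation). The other 6 lists did not pass, among them the cell cycle list with 9 higher and 5 lower of 40. Mesothelial markers fell in 3 of 5 cases (4 adjusted over the list alone), Upk1b by 1.73 and Krt19 by 1.43 on the log2 scale and Upk3b with them, while the adventitial markers Pdgfra (0.61), Dpt (1.76) and Lum (2.93) rose and Cd34 (-1.06) and Gsn fell. Of the endothelial markers Pecam1 (-0.55) and Emcn (-0.53) fell and Kdr (0.65) rose, the call of Kdr being lost without scramble TGF-β replicate 3. The Schwann cell marker Cdh19 averaged 0.204 CPM in scramble and 9.12 CPM in siRNA cells.

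In PDGF-BB medium Itgav siRNA lowered all 4 contractile genes of the panel. Tagln fell from 333 ± 11.4 to 73.4 ± 3.27 CPM (-2.18 ± 0.059), Acta2 from 393 ± 12.5 to 125 ± 3.43 CPM (-1.66 ± 0.043), Cnn1 from 8.83 ± 1.16 to 3.11 ± 0.864 CPM (-1.52 ± 0.17) and Myl9 by 2.13 on the log2 scale. Itgb8 (ENSMUSG00000025321, chromosome 12, 119158022 to 119238802, minus strand) rose 13.7-fold, from 3.36 ± 0.187 to 46.1 ± 4.97 CPM (3.77 ± 0.14). Spp1 rose 3.42-fold to 2160 ± 32.9 CPM, and Eln fell from 262 ± 8.04 to 152 ± 12.8 CPM (-0.79 ± 0.051). The interferon-stimulated genes Mx1 (7.36 ± 0.51), Rsad2 (6.84 ± 0.3), Ifi44 (6.61 ± 0.28), Iigp1c (6.31 ± 0.3) and Oasl2 (6.19 ± 0.23) rose most, Ifi44 from 4.01 ± 0.455 to 392 ± 59.7 CPM. Each change given a value in this paragraph had an adjusted p of 1.1e-07 or less in edgeR's test.

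Armcx2 (-3.59 ± 0.061), Nkain4 (-3.26 ± 0.09), Crct1 (204 ± 8.4 to 24 ± 1.5 CPM) and Map3k7cl (-2.92 ± 0.13) fell furthest after Itgav. Itgb3 rose 2.28-fold, Fn1 1.87-fold, Itga5 1.39-fold, Itgb5 1.3-fold and Itgb1 1.29-fold, Mki67 fell to 0.659 of the scramble level, and Myh11 changed by -0.55 ± 0.15 (edgeR adjusted p = 0.0029). Col1a1 (0.06) did not pass, and Klf4 rose by 0.15 with edgeR adjusted p = 0.0077, lost at 0.053 with no low-count filter. In all 9394 genes passed, 4659 higher and 4735 lower, with 1271 and 717 at least 2-fold, and 8795 passed without scramble PDGF-BB replicate 1.

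All 30 interferon response genes rose here too, with a median of 4.82 and Ifit3 going from 38 to 1980 CPM (camera adjusted p = 1.6e-17, and adjusted p = 0.11 with an estimated correlation). Focal adhesion genes fell in 22 of 28 cases, with Actn4 (-1.22), Fermt2 (-1.20) and Parva (-1.08) among them, and Tns2 and Nedd9 rose (camera adjusted p = 3.7e-09, and adjusted p = 0.017 with an estimated correlation). Cholesterol synthesis genes fell in 17 of 20 cases, with a median of -0.86, Idi1 at -1.66 and Sc5d at -1.10, and Insig1 rose (camera adjusted p = 2.3e-09, and adjusted p = 0.017 with an estimated correlation). Integrin subunits rose in 13 of 17 cases, Itga10 by 1.12, and Itga3 (-0.81) and Itga11 fell (camera adjusted p = 0.00017, and adjusted p = 0.028 with an estimated correlation). Cell cycle genes fell in 30 of 40 cases and Mcm6 rose, with Ccne1 at -0.96 and Mcm7 at -0.76 (camera adjusted p = 1.1e-05, and adjusted p = 0.22 with an estimated correlation). Contractile genes fell in 15 of 23 cases, and Itga8, Csrp1, Synpo2 and Mylk rose (camera adjusted p = 0.00062, and adjusted p = 0.091 with an estimated correlation). Inflammatory genes rose in 14 of 20 cases, with Ccl7 at 2.43 and C3 at 1.68, and Tnfaip3 (-1.30) and Icam1 fell (camera adjusted p = 0.0091, and adjusted p = 0.08 with an estimated correlation). Extracellular matrix genes rose in 22 of 39 cases, with Col3a1 at 1.39 and Emilin1 at 0.97, and fell in 10 (camera adjusted p = 0.045, and adjusted p = 0.55 with an estimated correlation).

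The other 9 lists did not pass, among them YAP and TEAD targets with 6 higher and 12 lower of 22, where Ankrd1 (-2.39), Ccn1 (-1.72) and Amotl2 (-1.25) fell and Gadd45a (1.89) rose, and ATF4 and ER stress genes, where camera pointed down against a mean of 0.03 and Slc7a11 (3.39) rose while Psat1 (-1.74) and Phgdh (-1.33) fell. Of 25 proteases and inhibitors 15 rose, including Mmp13 (2.90) and Timp3 (1.48), and 7 fell, including Plau (-2.22), with camera adjusted p = 0.06. Mesothelial markers fell in 4 of 5 cases, with Upk1b at -1.99, Msln at -1.36, Krt19 at -0.86 and Upk3b at -0.71, and endothelial markers in 6 of 10, including Tie1 (-0.64) and Esam (-0.53). The adventitial markers Lum (4.14), Scara5 (1.54), Pdgfra (1.26), Dpt and Gsn rose and Cd34 (-0.94) fell. The Schwann cell marker Cdh19 rose by 4.53, S100b rose and Mbp (-1.10) fell.

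**Figure D4:**
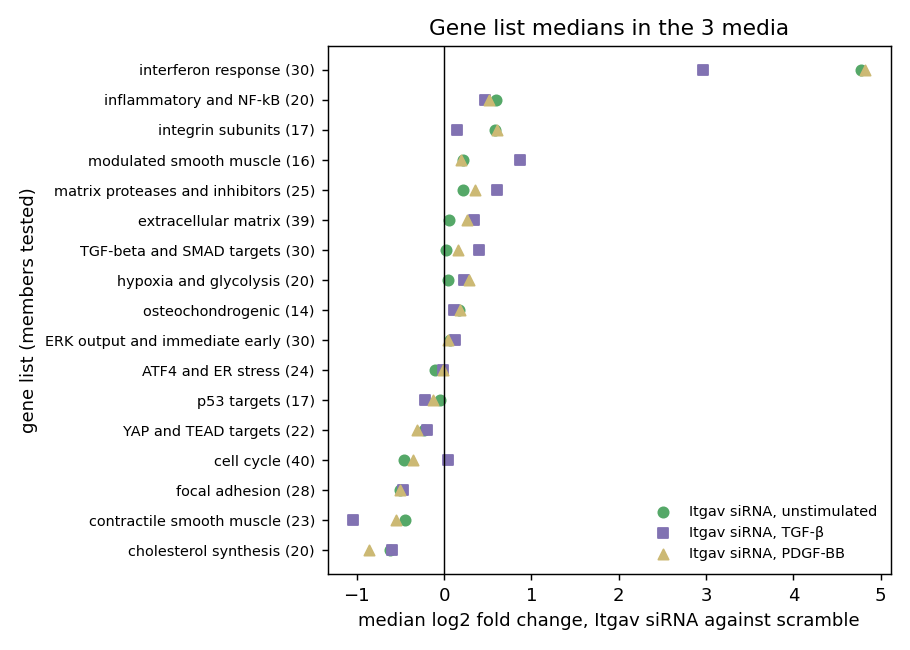
Median log2 fold change of Itgav siRNA against scramble (horizontal axis) over the tested members of each of the 17 pathway lists (vertical axis, with the number of members), as circles, squares and triangles for the 3 media. Interferon response genes lie furthest to the right, at medians of 4.77, 2.96 and 4.82 in unstimulated, TGF-β and PDGF-BB cells, and the cholesterol synthesis medians are -0.62, -0.6 and -0.86.

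Much of the siRNA effect recurred between media, whose siRNA comparisons share no library. Across genes the log2 fold changes correlated with r = 0.573 between unstimulated and TGF-β cells, 0.754 between unstimulated and PDGF-BB cells and 0.576 between the stimuli. Of genes called in both unstimulated and TGF-β cells, 2411 were higher in both, where independent lists would share 988.3, 2776 were lower in both, against 1058, and 402 of 5589 moved in opposite directions. For unstimulated and PDGF-BB cells these numbers were 3122 against 1209, 3356 against 1301, and 194 of 6672. For the stimuli they were 2503 against 1121, 2688 against 1152, and 538 of 5729. In all 3 media 2046 genes were higher and 2353 lower with the siRNA, and 334 were called in all 3 with mixed directions. The TGF-β response itself correlated between scramble and siRNA cells with r = 0.73 and a slope of 0.921 across genes, and the PDGF-BB response with r = 0.568 and a slope of 0.576.

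Whether the siRNA effect differed between media was tested as the difference between its log2 fold change under a stimulus and that in unstimulated cells. For TGF-β the fall of Acta2 was of like size in both (difference -0.01 ± 0.058, edgeR adjusted p = 0.91), while Myh11 fell further with TGF-β (-1.75 ± 0.17) and Spp1 rose further (2.44 ± 0.1). Gadd45a, induced by growth arrest and DNA damage, differed by 2.39 ± 0.078 and the filament protein gene Nes by 1.98 ± 0.062, and the activin subunit Inhbb differed by -2.45 ± 0.094 and the vessel growth factor Angpt2 by -2.26 ± 0.088. Each of the called genes in this paragraph had an adjusted p of 8.5e-08 or less in edgeR's test. In all 3678 genes passed, 1933 with a higher and 1745 with a lower siRNA effect under TGF-β. Interferon genes differed downward in 18 of 30 cases (22 adjusted over the list alone), with a median of -1.84 (camera adjusted p = 3.1e-10, and adjusted p = 0.24 with an estimated correlation), and cell cycle genes upward in 27 of 40 (31 adjusted over the list alone), with a median of 0.48 (camera adjusted p = 1.5e-12, and adjusted p = 0.074 with an estimated correlation). The call of TGF-β and SMAD targets, upward in 18 of 30 cases and downward in 5, was the one that held with an estimated correlation (camera adjusted p = 5.5e-06, and adjusted p = 0.0023 with an estimated correlation).

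For PDGF-BB the contractile genes Acta2 and Tagln fell further under the stimulus than without it, by -0.63 ± 0.059 and -0.78 ± 0.08 on the log2 scale, and Eln differed by -0.97 ± 0.071. Slc22a23 (2.29 ± 0.11), the cell adhesion gene Kirrel3 (2.2 ± 0.14) and Spp1 (1.49 ± 0.098) differed upward, and the matrix signalling protein Ccn1 downward (-1 ± 0.058). Itgb8 rose further with PDGF-BB (1.05 ± 0.21, edgeR adjusted p = 0.0014), and Itgav itself fell less far (0.58 ± 0.12, edgeR adjusted p = 0.0025). In all 2981 genes passed, 1505 upward and 1476 downward, and 2229 passed without scramble PDGF-BB replicate 1. None of the 30 interferon genes passed in edgeR's test here, the list median being 0.23 (camera adjusted p = 0.67). Contractile genes differed downward in 7 of 23 cases (9 downward and 2 upward adjusted over the list alone; camera adjusted p = 0.012, and adjusted p = 0.51 with an estimated correlation).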

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

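What drew attention here was a test of the difference between media: whether the log2 fold change of Itgav siRNA under a stimulus departs from that in unstimulated cells. For TGF-β 3678 genes passed edgeR's quasi-likelihood test on this difference. Genes with a higher siRNA effect under TGF-β were Spp1 (2.44), Gadd45a (2.39), Lhfpl2 (2.02), Nes (1.98) and the cell death gene Pmaip1 (1.90), whose 3′ UTR holds ACGTGAA and GACTACA of the Itgav mRNA, and in the panel Col1a1 (0.55), Itga5 (0.55), Mki67 (0.43), Fn1 (0.38), Eln (0.38), Tagln (0.28) and Itgb1 (0.25). Those with a lower effect were Inhbb (-2.45), Angpt2 (-2.26), Gpm6a (-1.78), the myelin gene Pmp22 (-1.60) and Tmt1a (-1.28), and in the panel Myh11 (-1.75) and Klf4 (-0.91). For Spp1 the siRNA raised the level 6.59-fold with TGF-β and 1.22-fold without a stimulus. Cnn1 (-0.44), Itgav (0.11), Itgb3 (0.16), Itgb5 (0.03) and Itgb8 (-0.35) did not pass, though Itgb8 did without scramble unstimulated replicate 2 (-0.63, edgeR adjusted p = 0.047) and Cnn1 without siRNA unstimulated replicate 2 (-0.58) or siRNA TGF-β replicate 1 (-0.55). Cnn1 also passed with no low-count filter (-0.45, edgeR adjusted p = 0.013) and with only the groups compared in the fit (-0.44, edgeR adjusted p = 0.041).

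Lists tested by camera on the same difference were called upward for cell cycle (adjusted p = 1.5e-12), TGF-β and SMAD targets (5.5e-06), extracellular matrix (2.1e-05), cholesterol synthesis (0.0012), modulated smooth muscle (0.011), matrix proteases and inhibitors (0.016), hypoxia and glycolysis (0.032) and osteochondrogenic genes (0.036). They were called downward for interferon response (adjusted p = 3.1e-10), contractile smooth muscle (3.2e-06) and p53 targets (0.025) in camera. With an estimated correlation the call of TGF-β and SMAD targets alone held, at adjusted p = 0.0023 in camera. In the cell cycle list the siRNA lowered 31 of 40 genes without a stimulus and 5 with TGF-β.

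For PDGF-BB 2981 genes passed edgeR's test on the difference. Higher were Slc22a23 (2.29), Kirrel3 (2.2), Gadd45a (1.57), Spp1 (1.49), Alcam (1.34), Itgb8 (1.05), Itgav (0.58), Itga5 (0.48) and Itgb3 (0.44). Itgb1 differed by 0.18 (edgeR adjusted p = 0.016), a call lost without scramble unstimulated replicate 2 (adjusted p = 0.057) or siRNA PDGF-BB replicate 3 (adjusted p = 0.052). Lower were Angptl7 (-1.61), Wwc1 (-1.15), Ccn1 (-1), Eln (-0.97), Cnn2 (-0.96), Cavin2 (-0.82), Tagln (-0.78), Acta2 (-0.63) and Itgb5 (-0.53). Fn1 (0.27), Col1a1 (0.21), Cnn1 (-0.54), Myh11 (-0.35), Mki67 (-0.11) and Klf4 (-0.01) did not pass. Fn1 passed in 4 alternative fits, Col1a1 in 5 and Cnn1 in 4: without scramble PDGF-BB replicate 2 Fn1 stood at 0.36 and Col1a1 at 0.27 (edgeR adjusted p = 0.015 and 0.018), and without siRNA PDGF-BB replicate 3 Cnn1 stood at -0.78 (edgeR adjusted p = 0.024). Camera called contractile genes downward (adjusted p = 0.012) and extracellular matrix genes (0.031) and integrin subunits (0.031) upward. With an estimated correlation these became adjusted p = 0.51, 0.77 and 0.51 in camera.

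Regrouping tests were chosen before their result was seen. Among 100 drawn regroupings of the TGF-β and unstimulated libraries, 2, counting the real one, gave at least as many genes as the 3952 of the real grouping in a fit of those libraries, the highest reaching 4001. For PDGF-BB 5 of 100, again counting the real one, reached the real 2747, the highest giving 4818, a share of 0.05. The other regroupings that reached the real counts all kept the real siRNA labels within a medium and so contain the siRNA effect of that medium. The 80 and 84 that mixed the labels in both media gave at most 0 genes in edgeR's test, but there the siRNA effect falls within the groups and widens their spread. Neither kind stands for a lack of difference alone, so these shares do not decide whether either count is due to chance. For the comparisons between a pair of groups only 10 splits of 6 libraries exist, so that the share cannot fall under 0.05: the real split was the 1 that reached its own count, with 7290 genes for TGF-β, 4920 for PDGF-BB, 8687 for the siRNA in unstimulated cells, 7524 with TGF-β and 8699 with PDGF-BB, and the highest other split gave 0 in edgeR's test each time. Every other split mixes the real groups, so their difference widens the spread, and the 0 calls lend no separate support.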

How the results depend on the processing

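Changing the gene filter, the scaling, the tool or the libraries left the number of called genes within 1.5-fold in every comparison, and no named gene reversed its direction among called results. The alternative with the largest effect was camera with an estimated correlation: list calls went from 10 to 3 for TGF-β, from 9 to 1 for PDGF-BB, from 7 to 2 for the siRNA in unstimulated cells, from 11 to 4 with TGF-β and from 8 to 3 with PDGF-BB. For the differences between media they went from 11 to 1 for TGF-β and from 3 to 0 for PDGF-BB. By construction an estimated correlation widens the error of a list whose genes vary together.

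With a mean of at least 1 CPM the correlation of the TGF-β and PDGF-BB responses was 0.0452 in place of 0.144. Those of the siRNA effect were 0.691 in place of 0.573 between unstimulated and TGF-β cells, 0.841 in place of 0.754 between unstimulated and PDGF-BB cells, and 0.689 in place of 0.576 between the stimuli. The cause was not tested.

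Leaving out a library gave correlations of 0.126 to 0.22 for the stimuli, 0.547 to 0.565 for the siRNA effect between unstimulated and TGF-β cells, 0.713 to 0.747 between unstimulated and PDGF-BB cells and 0.541 to 0.583 between the stimuli. The cause was not tested. Counts of called genes ranged from 6836 to 7494 for TGF-β, 4672 to 5682 for PDGF-BB, 7746 to 7916 for the siRNA in unstimulated cells, 6926 to 7082 with TGF-β, 8658 to 9142 with PDGF-BB, and 3096 to 3697 and 2155 to 3471 for the differences between media.

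A block for the replicate number gave 7779, 5909, 8582, 7783 and 9513 genes in the same order and 3893 and 3349 for the differences, with block correlations of 0.145, 0.576, 0.754 and 0.578 and 9, 10, 7, 11, 8, 11 and 3 list calls. With the block and an estimated correlation camera also called extracellular matrix (adjusted p = 0.022) and osteochondrogenic genes (0.04) for TGF-β, contractile genes for PDGF-BB (0.042), and proteases and inhibitors (0.044) and inflammatory genes (0.043) for the siRNA with TGF-β and with PDGF-BB, while cholesterol synthesis for the siRNA with TGF-β went from 0.032 to 0.05. Libraries of different groups with the same replicate number were not clearly more alike than others. Their 45 correlations of residuals lay between -0.088 and 0.097, against -0.1 to 0.096 for different numbers. That does not exclude shared cultures or days, on which the labels are silent.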

Other observations

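In the deposited KEGG pathways, tested with limma's camera and an estimated correlation over 297 pathways of 15 to 200 genes, TGF-β in scramble cells raised genes that build sugar chains and handle secreted proteins. Of 20 genes for chondroitin and dermatan sulfate synthesis, which makes the chains of matrix proteoglycans, 15 rose and 1 fell, with a median log2 fold change of 0.65 (camera adjusted p = 0.017), Chsy1, Chpf2, Chst3 and Chst11 among them. Of 155 genes for protein processing in the ER 95 rose and 18 fell (median 0.23, camera adjusted p = 0.017), and of 27 for protein export 21 rose and 1 fell (median 0.3, camera adjusted p = 0.021).

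Lower with TGF-β were drug metabolism by cytochrome P450, with 31 of 38 genes lower and 1 higher (median -1.37, camera adjusted p = 0.017), Fmo2, Gstm1, Maoa and Aldh3a1 among them. Mismatch repair had 17 of 22 genes lower (median -0.56, camera adjusted p = 0.02), histidine metabolism 10 of 15 lower and 1 higher (median -0.69, camera adjusted p = 0.022) and retinol metabolism 17 of 30 lower and 4 higher (median -0.8, camera adjusted p = 0.049). In the other comparisons camera called 0 KEGG pathways. The lowest value in the siRNA comparisons was that of chondroitin and dermatan sulfate synthesis with TGF-β, 14 genes higher and 2 lower (median 0.55, camera adjusted p = 0.073).

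For the interferon response all tests here were chosen only after the result was seen. One candidate explanation is that the siRNA cultures held more macrophages. Of 6 genes abundant in macrophages, taken from the 12 markers listed, the highest group mean in siRNA cells was 0.109 CPM, which argues against it. That argument rests on these 6 genes. Of the other markers Lyz2, Cd68 and Cd14 exceeded 1 CPM, with higher means in siRNA than in scramble cells of each medium. Cd68 with TGF-β averaged 3.16 against 1.21 CPM, and Cd14 in unstimulated cells 5.15 against 3.58 CPM. Csf1r and Ptprc had lower means. No lymphocyte marker exceeded 0.594 CPM in unstimulated or PDGF-BB siRNA cells, which argues against more lymphocytes there, but with TGF-β, where the interferon median was lowest, Trbc2 alone reached 2.85 CPM against 0.361 CPM in scramble cells, and this part stays open. Another is that the cells sensed the Itgav siRNA itself, apart from the loss of Itgav. The labels tell apart 1 Itgav siRNA condition, so this remains open.

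For the contractile genes the test on cell shares was chosen only after the result was seen and the seed test before. A lower share of smooth muscle cells could lower these genes and would raise markers of other cells. The highest of the 3 mesothelial medians was -0.86. These markers also moved with the medium, Krt19 averaging 32.5, 7.9 and 92.4 CPM in unstimulated, TGF-β and PDGF-BB scramble cells. The medians therefore do not decide whether the share of mesothelial cells changed. The 10 endothelial markers had a median of -0.27 for the mean over the 3 media, where a lower share of smooth muscle cells would raise them. Single markers were mixed: Pecam1 fell in each medium, while Tek (0.81) rose without a stimulus and Kdr (0.65) with TGF-β. Erg averaged 7, 45.4 and 8.89 CPM in unstimulated, TGF-β and PDGF-BB scramble cells, so that these markers do not decide it either. Among adventitial markers Pdgfra and Dpt were higher and Cd34 lower with the siRNA in all 3 media, so that a change in adventitial cells stays open. Off-target action through short matches in the 3′ UTRs could also lower them. The members with the sequence ACGTGAA differed from those without by 1.3 in mean log2 fold change, in the upward direction and from a lone member, Itga8. The 20 members with none of ACGTGAA, GACTACA and TTCGGAT, the lowest Itgav sequences that do not overlap one another, had a median of -0.8. That argues against direct matches to these 3 sequences in the 3′ UTRs of those 20 members. The siRNA sequences are not known, so matches to other sequences or outside the 3′ UTRs stay open, as do indirect effects.

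For the genes lower with the siRNA in all 3 media the test on Itgav sequences was chosen before the result and that on the scramble siRNA only after the result was seen. Across 16159 sequences of 7 bases, that with the lowest z was ACGTGAA (z = -9.9, 418 genes), which lies in the Itgav mRNA (chromosome 2, 83801846 to 83801852, GRCm38), as do 31.4% of all those tested and 7 of the 10 lowest, so the match by itself carries little weight. Its z lay below the lowest of any sequence for TGF-β (-3.63) and PDGF-BB (-4.78), which is consistent with off-target action of an siRNA with that seed. Of its 418 holders 27.8% were lower in all 3 media, against 15.7% of 12071 genes with none of ACGTGAA, GACTACA and TTCGGAT. These sequences were picked on the same fold changes, so the shares add no separate support. The shares are also not adjusted for the length, GC content or expression of the genes, as the z was. The highest z, 7.87, belonged to CGGAGAA, absent from the Itgav mRNA, but TGF-β reached 7.32 with another sequence and the next highest, TGTCACT at 6.92, lies in the Itgav mRNA, so action of the scramble siRNA stays open.

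Regrouping tests were chosen before the result. The 10 splits of 3 with 3 libraries are too few for a share under 0.05, and the real split was the 1 that reached its count for TGF-β, for PDGF-BB and for the siRNA in each medium. Every other split mixes the real groups, which widens their spread, so this lends no separate support. For the differences between media 2 of 100 regroupings, the real one included, reached the real count with TGF-β and 5 of 100 with PDGF-BB. The others that did so contain the siRNA effect of a medium, so these shares leave chance undecided for both counts.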
